A study of Homo sapiens with 4 samples.

How the data were processed

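RNA was sequenced from 769-P, a human renal clear cell carcinoma line, carrying a doxycycline-inducible short hairpin RNA (shRNA) against USP35. The labels give 4 libraries in 2 groups of 2, untreated control and doxycycline at 1 µg/ml for 4 days. Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. All libraries carry the hairpin construct, and no library given doxycycline without the hairpin was analysed here.

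Each library came as 1 table of 58735 genes with the values deposited as FPKM, fragments per kilobase of gene length, scaled to library size, per the file headers. HISAT2 2.0.5, featureCounts 1.5.0-p3 and limma are named in the submitters' processing notes, with no role or order. The genome build, strandedness, filters and the way the library size was set were not given in the sources used here. Identifiers and coordinates of all 58735 genes were identical to GENCODE release 29 on GRCh38 (Ensembl release 94), which was used for annotation and transcript GC content. Because strandedness is unknown, reads of a gene and of an overlapping gene on the other strand cannot be told apart. Reads of near-identical copies can be split between them, which makes the values of the AKR1C genes, AKR1B10, the histone genes, the metallothioneins, HSPA1A and HSPA1B, IFNL2 and IFNL3 uncertain. MT-ATP8 and MT-ATP6 overlap.

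FPKM multiplied by the length in the file fell on whole multiples of 1 step per library for 100.0% of genes at a tolerance of 0.02 reads. Whole reads and depth were recovered from these steps. The libraries held 16319640 and 17244546 reads in the controls and 17481827 and 18764546 with doxycycline. The library size behind the deposited FPKM was 97.2%, 101.0%, 107.5% and 97.6% of these totals in the same order. For a gene of 2 kb, the limit that a count of 0 allows (3 reads) lay between 0.08 and 0.095 FPKM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The recovery step returned 100.0% of simulated read numbers for the 58735 genes of control replicate 1.

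Genes with a mean of at least 1 FPKM over the 4 libraries were kept, which left 12029 genes, 10228 of them protein-coding. Differences are doxycycline minus control on the log2(FPKM + 1) scale, which understates the change of low genes. Fold changes in FPKM are ratios of group means. The test was limma-trend (limma 3.58.1 in R 4.3.3), two-sided, with 2 residual degrees of freedom, no covariate and Benjamini-Hochberg adjustment over the genes kept. The threshold was an adjusted p under 0.05. A single value compared over 2 against 2 libraries cannot reach an exact two-sided permutation p below 0.333. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

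Before the data were examined, 39 gene lists with 953 members were fixed, and all 953 members matched a gene. Lists with at least 5 genes kept (34) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34. Members that rose or fell were counted both adjusted over all genes and adjusted over the list alone. List members are said to have risen or fallen by the count adjusted over the list alone. That adjustment does not correct for the number of lists, and a gene held by several lists, such as SLC7A11, counts in each. Lists not tested held 2 genes kept (metallothioneins), 1 (distal tubule and collecting duct markers), 1 (fibroblast markers), 0 (endothelial markers) and 0 (leukocyte markers).

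The genes named were set by a rule fixed in the same way. They are USP35, 14 genes chosen in advance, the 10 largest rises and 10 largest falls past the threshold (none passed), and for each list the 2 members with the lowest p among those that rose and among those that fell. Where none passed, the 2 members with the lowest p are given as values, except 1 member that is not reported here. Any other gene is said to have been chosen after its values were seen.

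The steps were tested on simulated data for doxycycline against control over 12029 genes. With the spread fitted over all 4 libraries, 14% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, and 9 of 123 calls were unchanged genes. With the spread between the 2 controls, the shares were 76% and 99%, with 13 of 188 calls on unchanged genes. These shares need not hold for the data, since differences shared by many genes of a library were not simulated. In the data MCM5 and GINS2, at ratios of 0.244 and 0.243, did not pass (limma adjusted p = 0.0573 for both). With either simulated spread a list lowered 1.5-fold was called and 0 of 30 unchanged lists were called. Simulated genes varied independently of each other, and the list test was run on simulated levels without counting error. It therefore cannot show how often camera at the preset correlation calls lists whose genes vary together.

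Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5 FPKM, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, empirical Bayes without trend or robust, leaving out each library, limma-voom on recovered reads, a minimum absolute log2 difference of 1, limma treat against a fold of 1.2, protein-coding genes alone, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were an adjustment for gene length and GC content, limma-voom with median-of-ratios library sizes or with library quality weights, and the removal of mitochondrially encoded genes. GC content was known for 99.96% of genes kept. No count of other splits of the libraries was made, since each group holds 2.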

Results

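Transcript levels were measured by RNA sequencing in 769-P renal clear cell carcinoma cells carrying an inducible shRNA against USP35, a ubiquitin-specific protease. The 2 control libraries were untreated, and the 2 doxycycline libraries came from cells given 1 µg/ml for 4 days to switch on the hairpin. Depth was 16319640 and 17244546 recovered reads in the controls and 17481827 and 18764546 with doxycycline. The comparison asked which transcripts differed after induction of the hairpin. The series title concerns regulated cell death and survival of these cells.

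USP35 (ENSG00000118369, GRCh38 chromosome 11, 78188812 to 78214711, plus strand) was lower in both doxycycline libraries than in both controls. Control replicates 1 and 2 held 3.31 and 4.19 FPKM, and doxycycline replicates 1 and 2 held 2.11 and 2.54 FPKM. The means were 3.75 ± 0.62 FPKM (SD, n = 2) and 2.33 ± 0.30 FPKM (SD, n = 2), a ratio of 0.62. These values rested on 275, 382, 208 and 243 reads. The log2 difference was -0.51 with a standard error of 0.20, and did not pass the test (limma unadjusted p = 0.0414, adjusted p = 0.256). The gene overlaps KCTD21 on the minus strand by 11 bases, of a gene length of 5233 bases. KCTD21 stood at 1.82 and 1.5 FPKM in the controls and 1.88 and 2.88 FPKM with doxycycline.

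Across genes, no single gene passed the threshold, while many lay just above it, most of them lower with doxycycline. Of 12029 genes, 0 had a limma adjusted p under 0.05, with a lowest value of 0.0573, and 126 lay under 0.06 (104 lower, 22 higher). At an unadjusted p under 0.05 there were 2204 genes, 778 higher and 1426 lower, against 601 expected by chance. Both doxycycline libraries lay above both controls for 2926 genes and below both for 3478 genes, 53.2% together, against 33.3% by chance. The chance values of 601 genes and 33.3% are averages. Genes of a library vary together, so how far such counts stray from these averages by chance cannot be judged from 4 libraries. On recovered reads limma-voom called 0 genes with library totals, 121 with median-of-ratios library sizes and 228 with library quality weights. The count moved with the filter, the adjustment and the libraries entered. It was 242 (38 higher, 204 lower) over protein-coding genes alone, 261 (42 higher, 219 lower) over genes with a mean of at least 5 FPKM, and 341 (62 higher, 279 lower) after the adjustment for length and GC content. It was 0 without either control, 3942 without doxycycline replicate 1 and 1605 without doxycycline replicate 2. Counts over a list alone moved likewise, with at least 1 member past in 20 of 34 lists over all 4 libraries, 5 and 6 without control replicates 1 and 2, and 33 and 29 without doxycycline replicates 1 and 2.

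The 2 doxycycline libraries differed from each other by more genes than the controls did. Doxycycline replicate 2 lay farther from the controls than from replicate 1, while replicate 1 lay nearer to both controls than to replicate 2. Between them, 814 genes (6.8%) differed by at least 2-fold, against 135 (1.1%) between the controls, 782 and 686 between doxycycline replicate 1 and controls 1 and 2, and 1546 and 1123 for doxycycline replicate 2. Across genes, Pearson's r was 0.984 between the controls and 0.930 between the doxycycline libraries, although genes are not independent replicates. It was 0.942 between doxycycline replicate 1 and each control, and 0.908 and 0.922 between doxycycline replicate 2 and controls 1 and 2. Mitochondrially encoded genes took 8.21% and 8.50% of reads in the controls, 7.44% in doxycycline replicate 1 and 14.6% in doxycycline replicate 2. Ribosomal RNA made up 16.3% and 16.4% of these mitochondrial reads in the controls and 28.7% and 23.2% with doxycycline (exact permutation p = 0.333, the smallest the design allows).

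**Figure D1:**
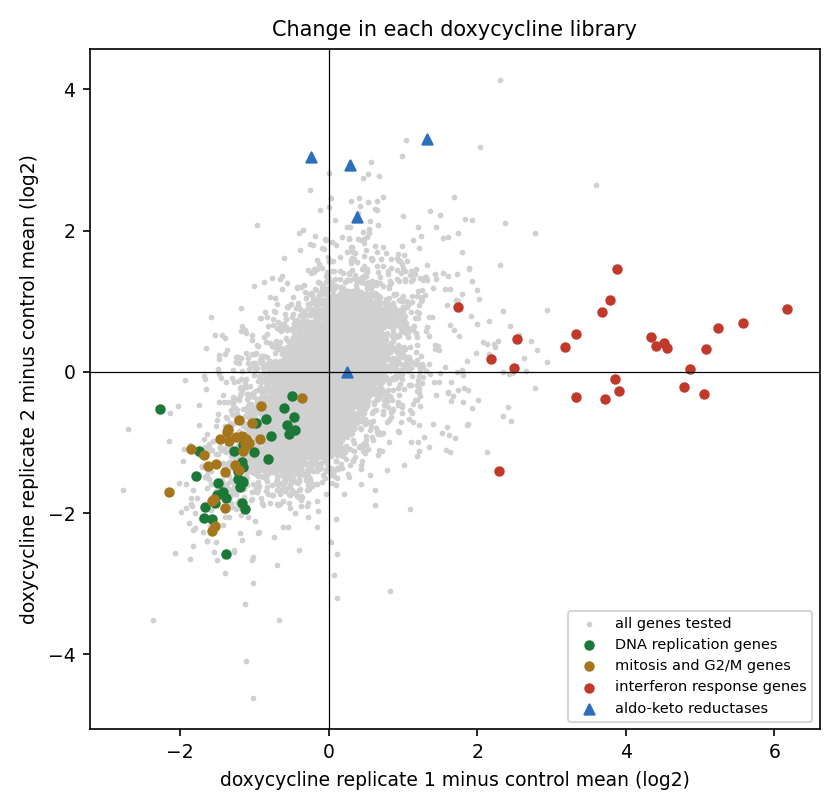
Each point is a gene, placed by its log2(FPKM + 1) in doxycycline replicate 1 (x axis) and replicate 2 (y axis) minus the mean of the 2 controls, for the 12029 genes tested. Replication and mitosis genes lie below 0 on both axes, interferon response genes lie far to the right, and 4 of the 5 aldo-keto reductases in the list of NRF2 targets lie high on the y axis.

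Genes of DNA replication and mitosis were lower in both doxycycline libraries. Of 34 replication genes kept, 32 fell and 0 rose when adjusted over the list alone, and 0 passed over all genes. MCM5, a subunit of the replicative helicase, went from 22.6 ± 1.28 to 5.51 ± 1.25 FPKM (SD, n = 2 each), and GINS2, a subunit of the same complex, from 15.4 ± 2.37 to 3.73 ± 0.57 FPKM. The list's median log2 difference was -1.36, with -1.17 in doxycycline replicate 1 and -1.38 in replicate 2 (camera adjusted p = 5.08e-23, and adjusted p = 0.576 with an estimated correlation). Of 29 mitosis and G2/M genes kept, 28 fell when adjusted over the list alone and 0 passed over all genes, with a median of -1.15 (-1.34 and -1.03 in the 2 libraries, camera adjusted p = 9.63e-22, and adjusted p = 0.576 with an estimated correlation). CENPA, the centromeric histone H3 variant, went from 13.2 ± 0.50 to 4.35 ± 0.03 FPKM, and PLK1, a mitotic kinase, from 41.8 ± 3.17 to 12.5 ± 1.71 FPKM. AURKB, the mitotic kinase chosen in advance, stood at 45.6 and 36.6 FPKM in the controls and 13.5 and 8.29 FPKM with doxycycline (limma adjusted p = 0.0587 over all genes). Without control replicate 1 the replication count was 22.

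Of the replication-dependent histone genes, the few kept mostly went the other way. Of 6 kept, 4 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. HIST1H2AC went from 2.96 ± 0.24 to 12.1 ± 2.37 FPKM and HIST1H2BK from 15.8 ± 0.75 to 35.6 ± 2.04 FPKM, while HIST2H2AC fell from 2.28 ± 1.35 to 0.62 ± 0.48 FPKM (SD, n = 2 each). The list median was 1.00 (camera adjusted p = 0.00218, and adjusted p = 0.576 with an estimated correlation). Some histone genes of this class also give polyadenylated transcripts outside S phase. Ribosomal RNA also made up more of the mitochondrial reads in both doxycycline libraries (28.7% and 23.2% against 16.3% and 16.4%). Without the filter on FPKM, over 18 members, the median was 0.0432, 2 rose and 0 fell over the list alone, and the camera adjusted p was 0.129, and without control replicate 1 only 1 gene rose. The fall of HIST2H2AC had an adjusted p of 0.0442 over the list alone, and 0 genes of the list fell without the filter, under quantile normalization, in all 3 voom fits, after the adjustment for length and GC content, or without control replicate 1 or doxycycline replicate 2.

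Among genes of oxidative stress and regulated cell death, SLC7A11, the cystine importer that restrains ferroptosis, was higher in both doxycycline libraries. It went from 3.68 ± 0.25 to 8.93 ± 1.27 FPKM (SD, n = 2 each), a ratio of 2.43 (limma adjusted p = 0.0696 over all genes and 0.0188 over the NRF2 list alone). Of 28 NRF2 targets kept, 5 rose when adjusted over the list alone, 0 fell and 0 passed over all genes. OSGIN1, a stress-induced growth regulator, was the other member with the lowest p, at 4.01 ± 0.30 and 8.94 ± 0.63 FPKM. The list median was 0.34, with 0.26 in doxycycline replicate 1 and 0.69 in replicate 2 (camera adjusted p = 2.51e-04, and adjusted p = 0.657 with an estimated correlation). The number that rose was 0 without either control, 15 without doxycycline replicate 1 (1 fell) and 6 without replicate 2. Doxycycline replicate 2, with the larger list median, also had the higher mitochondrial share.

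Of the genes chosen in advance, 0 of 15 including USP35 passed over all genes. NFE2L2, which encodes NRF2, stood at 17.5 ± 1.12 and 28.96 ± 9.82 FPKM (SD, n = 2 each), and KEAP1, which targets NRF2 for degradation, at 30.9 and 28.0 FPKM in the controls, 28.8 FPKM in doxycycline replicate 1 and 16.6 FPKM in replicate 2. Besides SLC7A11, both doxycycline libraries lay above both controls for NFE2L2, BIRC2, XIAP and GCLM, with log2 differences of 0.66, 0.33, 0.51 and 0.30. Besides USP35 and AURKB, they lay below both controls for TFRC, the transferrin receptor, with -0.42. Over all genes tested, 53.2% were separated in this way, so separation alone does not set these genes apart. The libraries overlapped for KEAP1, BIRC3, GPX4, ACSL4, HMOX1, NQO1 and TXNRD1. Of these, HMOX1 was at 76.8 FPKM in doxycycline replicate 1 and 35.9 FPKM in replicate 2, against 43.9 and 33.6 FPKM in the controls. NQO1 was at 147 FPKM in replicate 1 and 252 FPKM in replicate 2, against 159 and 144 FPKM, and ACSL4 at 35.1 and 74.6 FPKM against 43.0 and 41.9 FPKM. TXNRD1 was at 121 and 203 FPKM against 130 and 126 FPKM, and BIRC3 at 5.02 and 10.6 FPKM against 10.0 and 8.90 FPKM. GPX4, the lipid peroxide reductase, had a log2 difference of -0.06 that became 0.0893 under quantile normalization, 0.31 after the adjustment for length and GC content and 0.0422 without mitochondrially encoded genes.

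**Figure D2:**
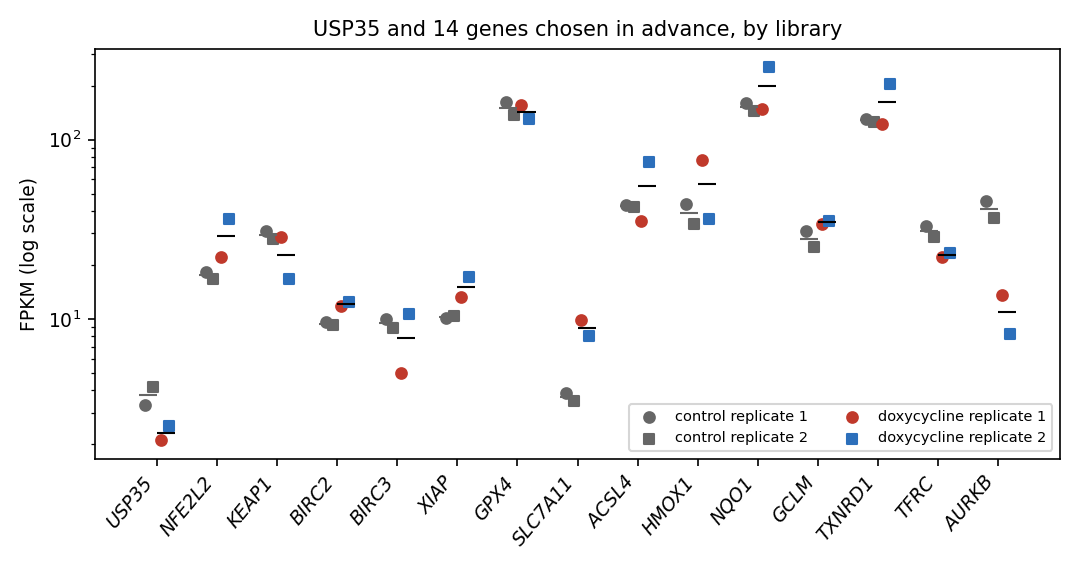
FPKM of USP35 and the 14 genes chosen in advance on a log axis, 1 point per library, with control means as grey bars and doxycycline means as black bars (n = 2 each). AURKB lies lower in both doxycycline libraries, at 13.5 and 8.29 FPKM, SLC7A11 lies higher at 9.83 and 8.03 FPKM, and the doxycycline libraries part for HMOX1, NQO1 and ACSL4.

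Further cell death lists did not pass camera over all 4 libraries with the main filter. Of 16 ferroptosis-restraining genes kept, 1 rose over the list alone (SLC7A11), and of 17 ferroptosis-promoting and response genes, 0 did, with SAT1 at 12.8 ± 2.06 and 23.0 ± 2.14 FPKM and NCOA4 at 70.9 ± 3.55 and 138 ± 49.6 FPKM (SD, n = 2 each). Of 22 glutathione and cysteine synthesis genes, 2 rose, SLC7A11 and GCLC, the catalytic subunit of glutamate-cysteine ligase, which went from 5.20 ± 0.50 to 13.0 ± 4.30 FPKM. BIRC5, or survivin, which also acts in mitosis, was the only 1 of 5 inhibitor of apoptosis genes to change over the list alone, and fell from 48.8 ± 7.95 to 14.3 ± 1.99 FPKM. Of 29 BCL2 family genes and apoptosis regulators, 0 passed, with TRAF2 at 20.01 ± 2.21 and 11.6 ± 4.39 FPKM and TNFRSF10B, a death receptor, at 52.9 ± 1.85 and 76.1 ± 4.79 FPKM. Of 7 necroptosis and pyroptosis genes, 0 passed, with IL18 at 0.75 ± 0.14 and 1.89 ± 0.21 FPKM and GSDMD at 15.2 ± 0.70 and 8.16 ± 3.90 FPKM. Camera adjusted p was 0.867 for the ferroptosis-restraining list, 0.200 for the promoting list, 0.146 for glutathione synthesis, 0.867 for inhibitors of apoptosis, 0.469 for the BCL2 family and 0.398 for necroptosis and pyroptosis. For the inhibitors of apoptosis the median was 0.22 and the mean -0.19, while the test pointed higher, and for the ferroptosis-restraining list the median was -0.07 and the mean -0.05 with the test pointing higher. The glutathione list had a camera adjusted p of 0.0288 with a mean of at least 5 FPKM, and the BCL2 list 0.0485 without doxycycline replicate 2. Without either control 0 ferroptosis-restraining and 0 glutathione genes passed over the list alone, while BIRC5's list kept a count of 1 that fell. Without doxycycline replicate 1, 3 ferroptosis-restraining genes rose and 3 fell, 5 promoting genes rose and 2 fell, 7 glutathione genes rose and 4 fell, and 2 BCL2 family genes rose and 8 fell over the list alone. Without replicate 2 these counts were 5 and 5, 3 and 0, 4 and 1, and 2 and 0. Of the necroptosis and pyroptosis genes, 1 rose and 2 fell without doxycycline replicate 1, 3 rose without replicate 2, 2 rose with voom on median-of-ratios sizes, and 2 rose and 1 fell with quality weights. Without the filter 0 glutathione and 0 ferroptosis-restraining genes rose over the list alone, and 1 glutathione gene rose under quantile normalization, without the trend and after the adjustment for length and GC content.

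Interferon response genes were far higher in doxycycline replicate 1 than in replicate 2. The median log2 difference of the 25 genes kept was 3.88 in replicate 1 and 0.36 in replicate 2, or 2.28 for both. IFITM1, an antiviral membrane protein, stood at 0.29 and 0.64 FPKM in the controls, 20.4 FPKM in doxycycline replicate 1 and 2.98 FPKM in replicate 2. Adjusted over the list alone 0 rose and 0 fell, and 0 passed over all genes. The camera adjusted p was 1.17e-07, and adjusted p = 0.857 with an estimated correlation. Over the list alone 14 rose with voom and library quality weights, 25 rose without doxycycline replicate 2, and 7 rose and 1 fell without doxycycline replicate 1, where the camera adjusted p was 0.0423. Of 17 antigen presentation genes 0 passed over the list alone, with medians of 0.78 in replicate 1 and -0.30 in replicate 2 (camera adjusted p = 0.171, and 2.25e-08 without doxycycline replicate 2). HLA-E stood at 23.8 ± 0.68 and 48.8 ± 10.5 FPKM, and NLRC5 at 5.05 FPKM in replicate 1 and 0.75 FPKM in replicate 2.

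Stress lists that passed camera also parted between the libraries or in their members. Of 25 ATF4 and integrated stress response genes, 1 rose over the list alone, SLC7A11, and 0 passed over all genes. The median was 0.69 in doxycycline replicate 1 and -0.25 in replicate 2 (camera adjusted p = 0.0201, and adjusted p = 0.909 with an estimated correlation). Of 19 heat shock genes, 1 rose over the list alone and 0 fell, with 0 over all genes, while the list median was -0.52 (camera adjusted p = 0.00322, and adjusted p = 0.857 with an estimated correlation). The controls also parted for this list, with a median of -0.31 for control replicate 2 minus control replicate 1. The gene that rose was CRYAB, a small heat shock chaperone, at 15.98 and 22.99 FPKM in the controls and 98.6 and 355 FPKM with doxycycline. The ATF4 camera adjusted p was 0.0782 without the filter, 0.0776 without control replicate 2 and 0.301 in the other direction without doxycycline replicate 1. For heat shock genes it was 0.0854 without control replicate 1 and 0.0890 without doxycycline replicate 1, and without either control 0 members of both lists passed over the list alone. Without doxycycline replicate 1, 4 ATF4 genes rose and 9 fell over the list alone, and without replicate 2, 18 rose and 0 fell. Over the list alone 0 heat shock genes rose without the filter or under quantile normalization, and 0 ATF4 genes rose without the filter. Heat shock genes that fell over the list alone numbered 8 after the adjustment for length and GC content, 3 with a mean of at least 5 FPKM, without the trend, with robust empirical Bayes and with voom on median-of-ratios sizes, and 2 with quality weights. They numbered 5 without doxycycline replicate 1 and 6 without replicate 2.

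Cholesterol synthesis and extracellular matrix genes were lower as lists with doxycycline. Of 23 cholesterol genes kept, 6 fell over the list alone and 0 rose, and 0 passed over all genes. LSS, lanosterol synthase, fell from 9.50 ± 0.69 to 3.59 ± 0.10 FPKM, and INSIG1, a sterol-regulated brake on the pathway, from 49.4 ± 2.79 to 15.99 ± 5.67 FPKM (SD, n = 2 each). The median was -0.45 (camera adjusted p = 1.22e-04, and adjusted p = 0.707 with an estimated correlation). Of 17 matrix genes, 6 fell over the list alone and 0 rose, with 0 over all genes, among them FBLN1, fibulin 1, from 11.4 ± 0.06 to 3.46 ± 0.86 FPKM and COL4A1, a basement membrane collagen, from 24.3 ± 3.01 to 11.5 ± 0.35 FPKM. The median was -0.35 (camera adjusted p = 0.0126, and adjusted p = 0.707 with an estimated correlation). The matrix median was -0.54 and -0.17 without control replicates 1 and 2, and -0.39 and -0.57 without doxycycline replicates 1 and 2. Over the list alone 0 genes of either list fell without control replicate 1 or without control replicate 2, 9 and 11 cholesterol genes fell without doxycycline replicate 1 and without replicate 2, and 2 matrix genes fell under either scaling. The matrix list's camera adjusted p was 0.0830 without control replicate 2. Without the filter, over 32 members, its median was -0.0134 and 2 fell over the list alone.

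Hypoxia, p53 and lysosome genes were higher as lists. Of 23 hypoxia and HIF targets, 2 rose over the list alone and 0 over all genes. They were CA12, a carbonic anhydrase, from 15.3 ± 2.82 to 54.0 ± 8.21 FPKM, and NDRG1, a hypoxia-induced stress gene, from 26.2 ± 0.81 to 86.9 ± 18.4 FPKM (SD, n = 2 each). The median was 0.38, with 0.36 in doxycycline replicate 1 and 0.11 in replicate 2 (camera adjusted p = 0.0126, and adjusted p = 0.576 with an estimated correlation). Of 24 p53 targets 0 passed over the list alone or over all genes, with CDKN1A, the cell cycle inhibitor p21, at 132 ± 7.86 and 283 ± 6.26 FPKM and MDM2, the p53 ligase, at 10.8 ± 0.25 and 19.2 ± 3.14 FPKM. The median was 0.23 (camera adjusted p = 0.0126, and adjusted p = 0.657 with an estimated correlation). It was 0.26 without control replicate 1 and 0.11 without control replicate 2. Over the p53 list alone 9 rose and 2 fell after the adjustment for length and GC content, 6 rose with library quality weights, 9 rose and 4 fell without doxycycline replicate 1, and 7 rose without replicate 2. Of 31 lysosome and autophagy genes 1 rose over the list alone and 0 over all genes, WIPI1, an autophagosome protein, from 3.20 ± 0.56 to 8.88 ± 1.33 FPKM, and the median was 0.14 (camera adjusted p = 0.0139, and adjusted p = 0.576 with an estimated correlation). Without doxycycline replicate 1 the camera adjusted p was 0.216 for hypoxia, 0.103 for p53 and 0.0768 for lysosome genes, and over the list alone 0 hypoxia genes rose without control replicate 1 and 0 lysosome genes without either control or without the filter. Without doxycycline replicate 1, 7 hypoxia genes rose and 3 fell and 8 lysosome genes rose over the list alone, and without replicate 2, 9 hypoxia genes rose and 1 fell and 3 lysosome genes rose.

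**Figure D3:**
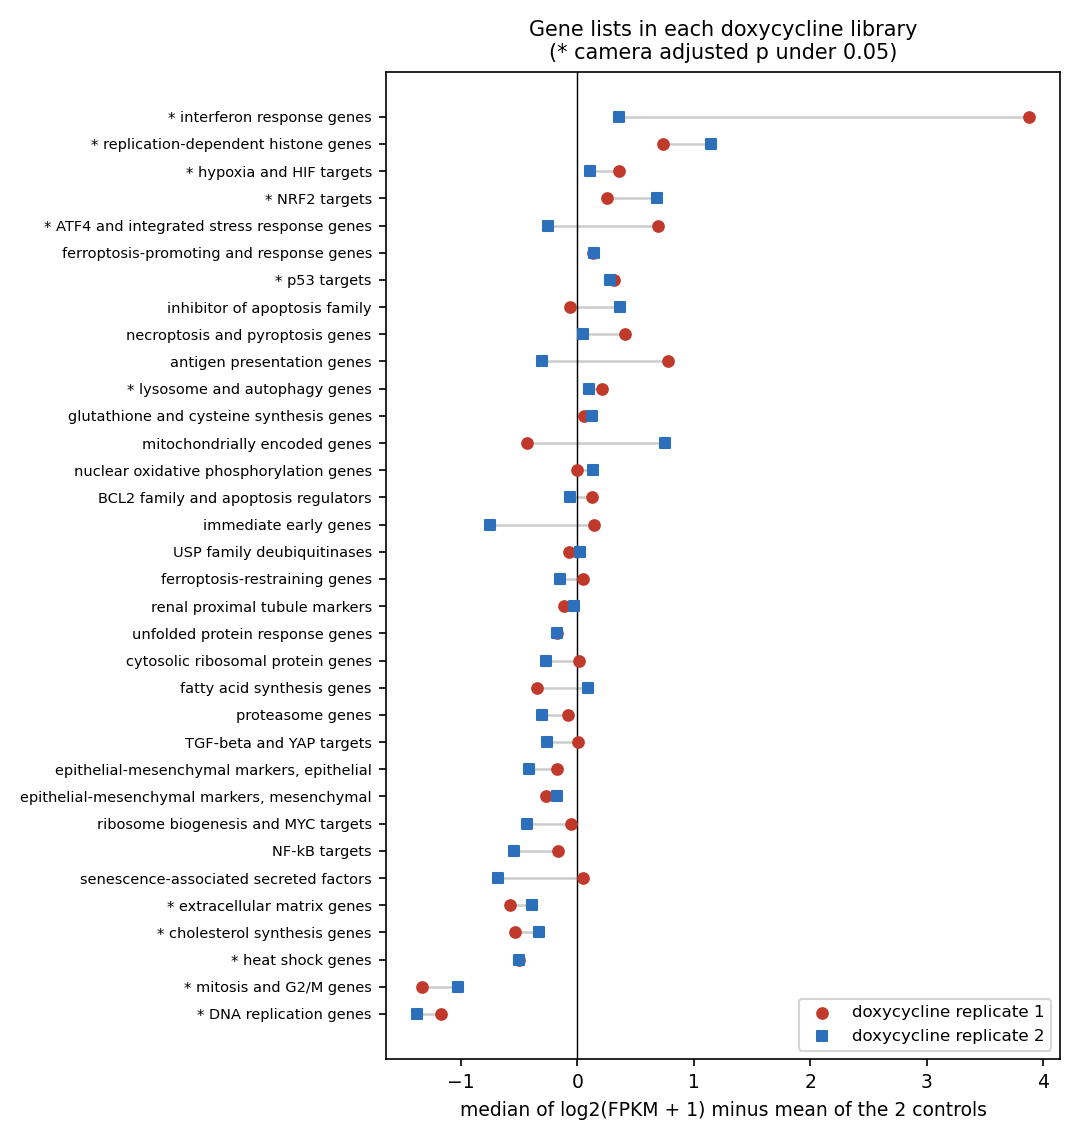
Median log2(FPKM + 1) difference from the control mean over the genes kept of each of the 34 lists tested, with doxycycline replicate 1 as red circles and replicate 2 as blue squares, and asterisks where camera's adjusted p was under 0.05. DNA replication (-1.17 and -1.38) and mitosis genes (-1.34 and -1.03) lie lowest in both, and the interferon list parts the libraries most (3.88 and 0.36).

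The other lists did not pass camera over all 4 libraries with the main filter. Single members that fell over the list alone were NFKB1 among 14 NF-kB targets (14.4 ± 0.06 to 6.31 ± 1.25 FPKM), JUNB among 17 immediate early genes (67.7 ± 8.83 to 19.4 ± 7.28 FPKM), and ANPEP, an aminopeptidase, among 8 proximal tubule markers (23.6 ± 0.01 to 8.38 ± 3.75 FPKM, SD, n = 2 each). Of 20 TGF-beta and YAP targets, ID2 rose from 8.999 ± 0.17 to 25.9 ± 2.59 FPKM and AXL, a receptor kinase, fell from 126 ± 7.84 to 42.0 ± 14.4 FPKM. Of 10 senescence-associated secreted factors, IGFBP3 rose from 3.45 ± 0.13 to 14.3 ± 4.57 FPKM and MMP1, a collagenase, fell from 3.64 ± 1.36 to 0.25 ± 0.03 FPKM. Of 8 mesenchymal markers, S100A4 and SNAI1 fell, from 7.72 ± 0.22 to 3.49 ± 0.72 FPKM and from 1.67 ± 0.39 to 0.42 ± 0.05 FPKM. Of 22 unfolded protein response genes DNAJB9, an endoplasmic reticulum chaperone, rose from 2.74 ± 0.67 to 6.58 ± 0.21 FPKM. Over all genes 0 of these passed, and camera adjusted p was 0.171, 0.623, 0.813, 0.420, 0.737, 0.323 and 0.661 for the NF-kB, immediate early, proximal tubule, TGF-beta, secreted factor, mesenchymal and unfolded protein lists. For the immediate early genes the median was 0.02 while the mean (-0.30) and the test pointed lower, and the adjusted p was 0.00889 without doxycycline replicate 1. Without control replicate 1 or without control replicate 2, 0 members of these lists passed over the list alone, except 1 rise and 1 fall among the secreted factors. The unfolded protein list also had 0 that rose without the filter, with a mean of at least 5 FPKM, under median-of-ratios scaling, without the trend, in all 3 voom fits and without mitochondrially encoded genes (adjusted p over the list alone 0.0460 for DNAJB9), and 4 of its genes fell after the adjustment for length and GC content. Without the filter 0 NF-kB, immediate early, TGF-beta, proximal tubule and mesenchymal genes fell over the list alone. The same held for NF-kB genes under quantile normalization and without mitochondrially encoded genes, for proximal tubule markers under quantile normalization and after the adjustment for length and GC content, for mesenchymal markers in 2 voom fits, and for secreted factors with a mean of at least 5 FPKM. Without doxycycline replicate 1, 2 NF-kB genes rose and 7 fell over the list alone, 1 immediate early gene rose and 10 fell, 1 TGF-beta target rose and 7 fell, 1 unfolded protein gene rose and 5 fell, 3 secreted factors rose and 5 fell, 1 proximal tubule marker rose and 1 fell, and 3 mesenchymal markers fell. Without replicate 2 these counts were 2 and 3, 5 and 3, 2 and 3, 1 and 0, 2 and 1, 0 and 2, and 0 and 2.

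Over all 4 libraries with the main filter, no member passed over the list alone in the remaining lists. The 13 mitochondrially encoded genes had medians of -0.43 in doxycycline replicate 1 and 0.76 in replicate 2 (camera adjusted p = 0.323 for both, and 0.00112 without doxycycline replicate 1), and the test turned lower under quantile normalization. MT-ATP8 stood at 124 ± 9.05 and 219 ± 60.2 FPKM and MT-ND2 at 3354 ± 166 and 4973 ± 1464 FPKM (SD, n = 2 each). Among 40 nuclear oxidative phosphorylation genes UQCRC2 stood at 42.7 ± 0.36 and 70.2 ± 22.7 FPKM and UQCRC1 at 74.8 ± 6.35 and 55.0 ± 9.06 FPKM (camera adjusted p = 0.418, and 0.0424 without control replicate 1). Camera adjusted p was 0.0924 for 29 ribosome biogenesis genes and MYC targets, with UTP20 at 10.3 ± 0.46 and 6.86 ± 0.18 FPKM and BOP1 at 50.3 ± 11.3 and 24.5 ± 11.5 FPKM. For that list it was 0.0220 without the filter, 0.0192 without control replicate 2 and 0.0418 without doxycycline replicate 1, where 12 members fell and 1 rose over the list alone. The camera adjusted p was 0.420 for 45 ribosomal protein genes, with RPL35 at 372 ± 78.3 and 220 ± 91.6 FPKM and RPS15 at 275 ± 43.3 and 191 ± 37.7 FPKM. The ribosomal protein test had a median of -0.10, pointed higher under quantile normalization and had an adjusted p of 0.0465 without control replicate 2. For 30 proteasome genes it was 0.146, with 0.0329 without the filter, 0.0154 without control replicate 2 and 0.00935 after the adjustment for length and GC content, with PSMD2 at 123 ± 21.7 and 64.9 ± 9.60 FPKM and PSMC3 at 64.5 ± 11.1 and 38.8 ± 8.29 FPKM. For 13 fatty acid synthesis genes it was 0.519, and 0.0156 without doxycycline replicate 2, with FASN at 86.9 ± 8.89 and 47.4 ± 0.70 FPKM and SREBF1 at 28.6 ± 3.15 and 22.9 ± 4.69 FPKM. For 10 epithelial markers it was 0.0838, with KRT18 at 56.2 ± 8.68 and 31.0 ± 0.45 FPKM and CRB3 at 14.6 ± 1.81 and 9.12 ± 1.65 FPKM. For 41 USP family deubiquitinases it was 0.481, with a median of -0.01, a mean of 0.04 and USP25 at 7.97 ± 0.02 and 12.5 ± 0.15 FPKM and USP7 at 20.6 ± 0.51 and 14.2 ± 1.41 FPKM.

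Markers of other cell types were few. No leukocyte or endothelial marker reached a mean of 1 FPKM, and 1 distal tubule marker (AQP3, 2.11 ± 0.68 and 0.83 ± 0.71 FPKM) and 1 fibroblast marker (ACTA2, 12.9 ± 1.94 and 7.24 ± 4.63 FPKM, SD, n = 2 each) did. The 2 metallothioneins kept were MT2A, at 299 and 153 FPKM in the controls and 225 and 28.3 FPKM with doxycycline, and MT1X, at 3.56 and 1.49 FPKM and 11.3 and 1.02 FPKM.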

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

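The adjustment for length and GC content, both voom weightings and the removal of mitochondrially encoded genes were chosen after seeing the data. The count of 0 genes past the threshold rested on adjusted p-values just above it. It became 261 with a mean of at least 5 FPKM and 242 over protein-coding genes, settings in which fewer genes were tested. With voom it was 121 on median-of-ratios library sizes and 228 with library quality weights. After the adjustment for length and GC content it was 341. With a mean of at least 5 FPKM the spread was also fitted anew, and the lowest limma adjusted p was 0.0224. For none of these settings was the cause of the changed count tested. It ranged from 0 (without either control) to 3942 (without doxycycline replicate 1) on leaving out 1 library. The lone library of a group was then assumed to vary like the other group, which is the control pair when a doxycycline library is left out. Genes at an unadjusted p under 0.05 numbered 1424 with a mean of at least 5 FPKM, where fewer genes were tested, and 659 to 5262 on leaving out 1 library. The count stayed 0 with the other pseudocounts, no filter, both scalings, empirical Bayes without trend or robust, voom with library totals, removal of mitochondrial genes, treat and a minimum log2 difference of 1. USP35 was lower and did not pass in any fit that held it, with log2 differences from -0.66 to -0.25, and it was not among genes with a mean of at least 5 FPKM. At that filter the necroptosis and histone lists and 6 other named genes gave no value, and lists were not tested with voom.

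The labels share replicate numbers but do not say that a number pairs libraries, and there are only 2 pairs (correlation of deviations 0.21). With the replicate number as a block the count was 784 (202 higher, 582 lower), the number of lists past camera stayed 12, and the inhibitor of apoptosis list turned direction (adjusted p = 0.984). Over the list alone 24 of 25 interferon genes then rose. The block leaves fewer residual degrees of freedom than the main fit, so its calls rest more on the spread pooled across genes. The interferon calls do not show an even rise, since the list median was 3.88 in doxycycline replicate 1 and 0.36 in replicate 2.

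Of the 12 lists past camera, 0 passed with an estimated correlation and 0 by fry for 1 direction. The adjusted p was 0.576 for both replication and mitosis genes and 0.857 for interferon genes with an estimated correlation, and 0.0761, 0.0761 and 0.654 by fry for 1 direction. By fry for either direction 18 of 34 lists passed, among them 8 of the 12, replication (0.0300), mitosis (0.0291), cholesterol (0.0291), NRF2 (0.0364), hypoxia (0.0213), p53 (0.0364), lysosome (0.0300) and histone genes (0.0364). Interferon (0.386), ATF4 (0.386), heat shock (0.0896) and matrix genes (0.0666) did not. This test does not compare a list with other genes. With so few libraries the tests for 1 direction have few residual degrees of freedom, and the cause was not tested.

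Of the results that turned direction, 1 had passed with all 4 libraries, the ATF4 list, at 8.16e-12 to 0.301 on leaving out 1 library, turned without doxycycline replicate 1. Without the filter the adjusted p of turned lists was 0.661 for ferroptosis-restraining, 0.781 for inhibitor of apoptosis, 0.822 for secreted factor and 0.179 for proximal tubule genes, and with a mean of at least 5 FPKM 0.567 for secreted factors. Quantile normalization turned the mitochondrially encoded (0.384) and ribosomal protein lists (0.858) and GPX4 (log2 0.0893). Length and GC adjustment turned the ferroptosis-restraining and inhibitor of apoptosis lists (0.883 each), the immediate early and USP lists (0.901 each), the proximal tubule list (0.642), GPX4 (0.31) and SREBF1 (0.0545). Removal of mitochondrial genes turned GPX4 (0.0422), and fry for 1 direction turned the inhibitor of apoptosis list (0.741). The cause was not tested for any of these.

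On leaving out 1 library, log2 differences ranged from -0.80 to 0.15 for BIRC3, -0.19 to 0.0628 for GPX4, -0.26 to 0.80 for ACSL4, -0.10 to 0.98 for HMOX1, -0.0376 to 0.73 for NQO1 and -0.0749 to 0.66 for TXNRD1, each turned by a doxycycline library, and GPX4 also without control replicate 1 (0.0567). Besides the ATF4 list, adjusted p of the lists that turned or crossed the threshold ranged from 0.726 to 0.954 (ferroptosis-restraining), 0.467 to 0.955 (inhibitor of apoptosis), 0.0485 to 0.597 (BCL2 family), 0.108 to 0.920 (necroptosis and pyroptosis), 0.301 to 0.779 (unfolded protein response), 0.0156 to 0.896 (fatty acid synthesis), 0.0192 to 0.562 (ribosome biogenesis and MYC targets), 0.0154 to 0.880 (proteasome), 0.00112 to 0.413 (mitochondrially encoded), 0.0424 to 0.891 (oxidative phosphorylation), 0.0465 to 0.726 (ribosomal protein), 0.0659 to 0.837 (TGF-beta and YAP), 0.00889 to 0.676 (immediate early), 2.25e-08 to 0.306 (antigen presentation), 0.228 to 0.880 (secreted factors) and 0.467 to 0.896 (proximal tubule). For lists past camera that crossed it was 0.00115 to 0.0890 (heat shock), 6.34e-05 to 0.216 (hypoxia), 0.00190 to 0.103 (p53), 0.00895 to 0.0768 (lysosome) and 2.32e-04 to 0.0830 (matrix). Over the list alone and all 4 libraries, without the block, the settings gave 28 to 34 replication and 26 to 29 mitosis genes that fell, 2 to 8 NRF2, 0 to 14 interferon and 0 to 9 p53 genes that rose, 4 to 9 cholesterol, 2 to 8 matrix and 0 to 8 heat shock genes that fell, and 2 to 4 hypoxia, 0 to 4 ATF4 and 0 to 3 lysosome genes that rose. Replication and mitosis genes kept their direction and their camera call on leaving out any library and under both scalings. Depth limits low genes, since 3 reads of a 2 kb gene stand for 0.08 to 0.095 FPKM.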

Other observations

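The tests of explanations in this part were chosen after the result was seen, except that for doxycycline without the hairpin. Genes here were chosen after their values were seen, other than CRYAB. Over protein-coding genes alone, 38 genes were higher and 204 lower at a limma adjusted p under 0.05, a set of genes tested that also sets the count. CRYAB had the largest log2 rise among them, 3.22, at 19.5 ± 4.96 and 227 ± 181 FPKM (SD, n = 2 each, limma adjusted p = 0.0467 over protein-coding genes and 0.0746 over all genes). TUBA1A, an alpha tubulin, went from 12.1 ± 0.77 to 61.3 ± 7.99 FPKM, EPAS1, which encodes HIF-2 alpha, from 2.79 ± 0.09 to 9.64 ± 3.54 FPKM, and ARRDC4, an arrestin-domain protein regulated by glucose, from 1.73 ± 0.01 to 7.82 ± 3.58 FPKM. Their limma adjusted p over protein-coding genes was 0.0338, 0.0467 and 0.0467, against 0.0573, 0.0731 and 0.0748 over all genes.

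Among the genes lower in both doxycycline libraries were 2 developmental transcription factors. LHX1, a kidney-lineage homeobox gene, went from 26.5 ± 1.2 to 5.87 ± 0.87 FPKM, and FOXC2, a forkhead gene, from 26.5 ± 4.10 to 4.91 ± 2.21 FPKM (SD, n = 2 each). UHRF1, which recruits maintenance DNA methylation, went from 21.1 ± 1.56 to 3.50 ± 1.06 FPKM and MYBL2, a cell cycle transcription factor, from 92.4 ± 5.82 to 20.6 ± 6.58 FPKM. NID1, a basement membrane protein, went from 44.9 ± 7.42 to 9.52 ± 5.41 FPKM, DPYSL3 from 331 ± 8.39 to 98.1 ± 15.8 FPKM, and SDC1, a heparan sulfate proteoglycan, from 18.9 ± 1.61 to 4.81 ± 1.25 FPKM. Over all genes, limma adjusted p was 0.0573 for LHX1, FOXC2, UHRF1, MYBL2, DPYSL3 and SDC1 and 0.0696 for NID1.

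DNA replication and mitosis genes were lower in both doxycycline libraries, with a median log2 difference of -1.29 over the 63 genes of both lists. Gene length and GC content as the whole cause is argued against by a median of -1.22 after each library was adjusted for them. Scaling between libraries is argued against by a median of -1.19 under the scaling that moved it most, the removal of mitochondrially encoded genes. The knockdown and the doxycycline itself cannot be told apart, since 0 libraries had doxycycline without the hairpin, and an effect of the hairpin on other targets was not tested.

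Interferon response genes were far higher in doxycycline replicate 1 than in replicate 2, where the list median was 0.36. ISG15 stood at 11.3 and 8.85 FPKM in the controls, 363 FPKM in replicate 1 and 7.89 FPKM in replicate 2, and IFIT1 at 2.38, 2.41, 161 and 4.51 FPKM. Leukocyte RNA is argued against, since the highest of 18 leukocyte markers in that library was 0.276 FPKM. Another cell line in place of that library's cells is argued against, since 1 protein-coding gene outside the interferon list was on or off in it alone. Such a gene had at least 2 FPKM in that library and under 0.1 FPKM in the others, or the reverse. That count cannot show another line mixed in as a part, since few genes would then pass both bounds. Transcription of interferon genes in that culture is a candidate explanation, with 44 reads of IFNB1, IFNL1, IFNL2 and IFNL3 against 1 in the other 3 libraries (exact two-sided binomial p = 1.2e-25, which compares libraries and covers counting error only). What set it off, a mislabelled 769-P library, and another line mixed in as a part stay open.

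Aldo-keto reductase genes were far higher in doxycycline replicate 2 than in replicate 1, with AKR1B10 at 52.7 and 48.7 FPKM in the controls, 42.7 FPKM in replicate 1 and 426 FPKM in replicate 2, AKR1C3 at 61.5, 67.6, 84.3 and 297 FPKM, and AKR1C1 at 2.99, 3.44, 9.56 and 40.4 FPKM. Another cell line in place of that library's cells is argued against, since 2 protein-coding genes (CGB8 and CST6) were on or off in it alone. Such a gene had at least 2 FPKM in that library and under 0.1 FPKM in the others, or the reverse. Another line mixed in as a part stays open, since few genes would then pass both bounds in that library. Renal tubule cells mixed into it stay open. Of 16 proximal tubule markers under 0.5 FPKM in the controls the highest, LRP2, reached 1.10 FPKM there (0.0388 and 0.0706 FPKM in the controls), against a smallest aldo-keto reductase rise of 19.96 FPKM, while SLC22A6, FBP1 and DPEP1 stood at 0. Genes of the same kind that were higher there included SLC34A1 (0.0418, 0.0761, 0.235 and 0.952 FPKM) and CUBN (2.06 FPKM, and 0.285 to 0.68 FPKM in the other 3). So were AQP1 (0.752, 1.14, 1.15 and 3 FPKM), SLC3A1 (0.559, 0.711, 0.724 and 1.67 FPKM), and outside the list MME (0.334, 0.4, 0.326 and 4.05 FPKM) and DAB2 (6.48, 8.47, 10.3 and 41.7 FPKM). The abundant markers GGT1, PAX8, SLC17A3, MIOX and ANPEP, at 49.1, 38.5, 26.5, 20 and 11 FPKM there, lay within or below the range of the other libraries. A general rise of NRF2 targets may contribute and stays open. The other 23 targets had a median of 0.46 there, above all 10000 random lists matched on expression. In replicate 1 their median was 0.22 and was not ranked, while the whole list of 28 lay above all random lists in both doxycycline libraries. That list includes the aldo-keto reductases, and both libraries were measured against the same control mean. Random lists drew genes independently, so these ranks do not allow for targets that vary together. No biological explanation in the design parts the 2 doxycycline libraries.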
